A study of Mus musculus with 20 samples.

How the data were processed

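The series profiled gene expression in cells sorted from the mammary gland of virgin female FVB/N mice aged 6 to 8 weeks. Per the labels' protocols, cells were dissociated from the fourth inguinal glands, depleted of lineage-positive cells with an enrichment kit, stained with fluorescent antibodies and a viability dye, and sorted on a flow cytometer. Each library was made from 1000 cells with the SMART-Seq V4 ultra low input kit, which amplifies cDNA from polyA RNA. Mammary repopulating units (MRU) are the basal-enriched cells of the CD24-medium, CD49f-high gate. CD24 is encoded by Cd24a and CD49f, integrin alpha 6, by Itga6. The 4 populations were MRU positive for CD200 and CD200R1 (CD200+CD200R1+ MRU), the MRU outside that gate (remaining MRU), cells outside the MRU gate positive for CD200 and negative for CD200R1 (CD200+ non-MRU), and cells outside the MRU gate negative for CD200 and positive for CD200R1 (CD200R1+ non-MRU). CD200 is a membrane glycoprotein and CD200R1 its receptor. Each population was sorted from 5 individual mice, numbered 2 to 6, which gave 20 libraries. Per the labels, the CD200R1+ non-MRU library of mouse 4 also received about 10% of its cells from mouse 3.

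Per the submitters' processing notes, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 were used with build GRCm38. Their order and parameters, the annotation release and the strand setting are not given in the sources used here. The deposited raw counts were whole reads per Ensembl gene and library, not normalized, per the file headers. The authors also deposited a normalized signal for each gene and library, which the file headers call counts normalized to library size. From the values, that signal was the raw count divided by 1 factor per library, and the factor equalled the median-of-ratios size factor to a relative difference of at most 1.8e-15. The deposited log2 fold changes of 4 comparisons were the authors' own. The deposited p-value and adjusted p-value columns belonged to the same 4 comparisons, per the file headers. The authors' values were used only for a count of genes below the threshold. All other results were computed from the deposited counts.

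The table held 46603 genes, of which 37171 had at least 1 count in any library. None of its lines lacked a gene. Library totals ran from 10853587 to 13862963 counts, so 3 counts in a single library corresponded to 0.216 to 0.276 CPM (counts scaled to a common library total). The floor used where a population had no count of a gene was lower, since it set 3 counts over all 5 libraries together. Reads carried no molecular identifiers that the sources name, so floors and counting intervals cover counting error only. Replicate libraries were compared in 40 pairs by a chi-square of their counts, to look for a library deposited more than once. It ranged from 13.02 to 93.29 per gene. Each library counted as 1 replicate, since the labels give 5 individual mice.

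Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 17236, and libraries were scaled by TMM. A single quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to all 20 libraries with the population as its only term. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD over 5 libraries, and fold changes come from the model with their standard error (SE) on the log2 scale. Where a population had no count of a gene, the fold is a lower bound set by 3 counts over the population. Where it had 1 to 3 counts, the ratio of the count rates is given with its exact 95% counting interval. Mean TMM factors were 1.08 in the CD200+CD200R1+ MRU, 1.05 in the remaining MRU, 1.08 in the CD200+ non-MRU and 0.81 in the CD200R1+ non-MRU. Without these factors the median log2 fold change of all genes moved from -0.056 to 0.365 between the non-MRU populations, from 0.008 to 0.431 between CD200+CD200R1+ MRU and CD200R1+ non-MRU, and from 0.025 to 0.407 between remaining MRU and CD200R1+ non-MRU. Changes are therefore relative to the TMM scaling.

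Gene lists for mammary cell types, other cell types and pathways were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives. Of 42 lists, the 39 for biological groups with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Adjusted p-values of lists are Benjamini-Hochberg values over the 39 lists. Camera was repeated with a correlation estimated from the residuals. Named genes are those past the threshold, with a mean of at least 10 CPM and no overlap between the libraries of the populations compared, that had the largest changes. There were 8 in each direction for the comparison within MRU and that between the non-MRU populations, and 5 in each direction for the others. Predicted genes and mitochondrial genes were left out of that part of the rule. The sort markers Cd200, Cd200r1, Cd24a and Itga6 are named in each comparison. For each list described, the members named are those past the threshold with the smallest adjusted p, up to 4 within MRU and up to 2 elsewhere. Some genes that the rule names are not reported here. All called lists are described for those main comparisons. Within MRU some lists that did not pass are described too, and they were not chosen by their adjusted p. For the others, the text describes called lists that held with an estimated correlation, or that mark other cell types or RNA quality, a choice made after the data were seen. Coordinates are 1-based gene bounds in GRCm38 from GENCODE M21, matched by Ensembl identifier.

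Populations of the same mouse share its number, since the series design states 5 individual mice. Over 8968 genes, deviations from the population means correlated within mice at a mean of 0.38 between the MRU populations, against -0.09 between different mice. In the other comparisons the same-mouse means were 0.12 to 0.16, against -0.04 to -0.03. The mouse number as a block was an alternative, so the main fit and the fits that left out a library did not use this pairing. The other alternatives were median-of-ratios scaling in edgeR, library size without scaling factors, no filter on low counts, the 10 libraries of the populations compared alone, DESeq2 1.42.0, voom with sample quality weights, and each library left out in turn. For lists they were also camera on ranks and the rotation test fry. The range of a list's adjusted p is over the alternatives with camera, since fry does not compare a list with other genes.

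The model was tested on simulated data, with counts drawn for the real genes and known changes in some of them. In the design of the comparison within MRU, 9% of genes changed 1.5-fold were recovered, 34.3% of those changed 2-fold and 68.2% of those changed 4-fold. Of 81 genes called there, 6 were unchanged, with 16849 tested. In the design of the non-MRU comparison the shares were 14.9%, 41.8% and 71.2%, and 8 of 95 genes called were unchanged, with 16828 tested. In each design 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, besides 1 list shifted together. The real comparisons called far more genes, 1424 within MRU and 9043 between the non-MRU populations. The adjusted p depends on how many genes change, so the shares recovered and falsely called do not carry over to the real comparisons. The simulated libraries carried no effect of the mouse.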

Results

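RNA was profiled in 4 sorted mammary populations of 5 mice each, 20 libraries in all. The populations were CD200+CD200R1+ MRU, remaining MRU, CD200+ non-MRU and CD200R1+ non-MRU. Library totals ran from 10853587 to 13862963 counts. The median number of genes detected was 24463 in CD200+CD200R1+ MRU, 23823 in remaining MRU, 23374 in CD200+ non-MRU and 24003 in CD200R1+ non-MRU. The mitochondrial genome took a mean of 4.3%, 3.74%, 2.74% and 2.79% of counts in the same order. Adjusted p-values are from edgeR for genes and camera for lists.

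The sort markers were examined first. Cd200 (ENSMUSG00000022661, chromosome 16, 45382135 to 45409053) stood at 199 ± 34.2 CPM (SD, n = 5) in CD200+ non-MRU, 198 ± 18.9 in remaining MRU, 102 ± 19 in CD200+CD200R1+ MRU and 3.54 ± 1.67 in CD200R1+ non-MRU. Cd200r1 (ENSMUSG00000022667, chromosome 16, 44765736 to 44794978) was low in all 4 populations, with 4.05 ± 2.44 CPM in CD200+ non-MRU, 2.76 ± 1.33 in CD200+CD200R1+ MRU, 1.62 ± 1.58 in remaining MRU and 0.864 ± 0.773 in CD200R1+ non-MRU. Its mRNA was thus lowest on average in a population sorted as positive for the protein. Cd200 was low in the CD200-negative population, but 1.95-fold higher in remaining MRU than in CD200+CD200R1+ MRU. The labels of remaining MRU can be read as negative for both proteins or as outside the double-positive gate, and an exchange of names between populations was not tested. Itga6 was highest in the MRU, at 1110 ± 147 CPM in CD200+CD200R1+ MRU and 815 ± 124 in remaining MRU, against 79.2 ± 14.2 in CD200+ non-MRU and 9.63 ± 4.39 in CD200R1+ non-MRU. Cd24a stood at 640 ± 174, 678 ± 79.3, 825 ± 120 and 19.4 ± 11.2 CPM in that order. The basal keratin Krt14 and the luminal keratin Krt8 had 0.744 ± 0.594 and 5.93 ± 7.92 CPM in CD200R1+ non-MRU.

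**Figure D1:**
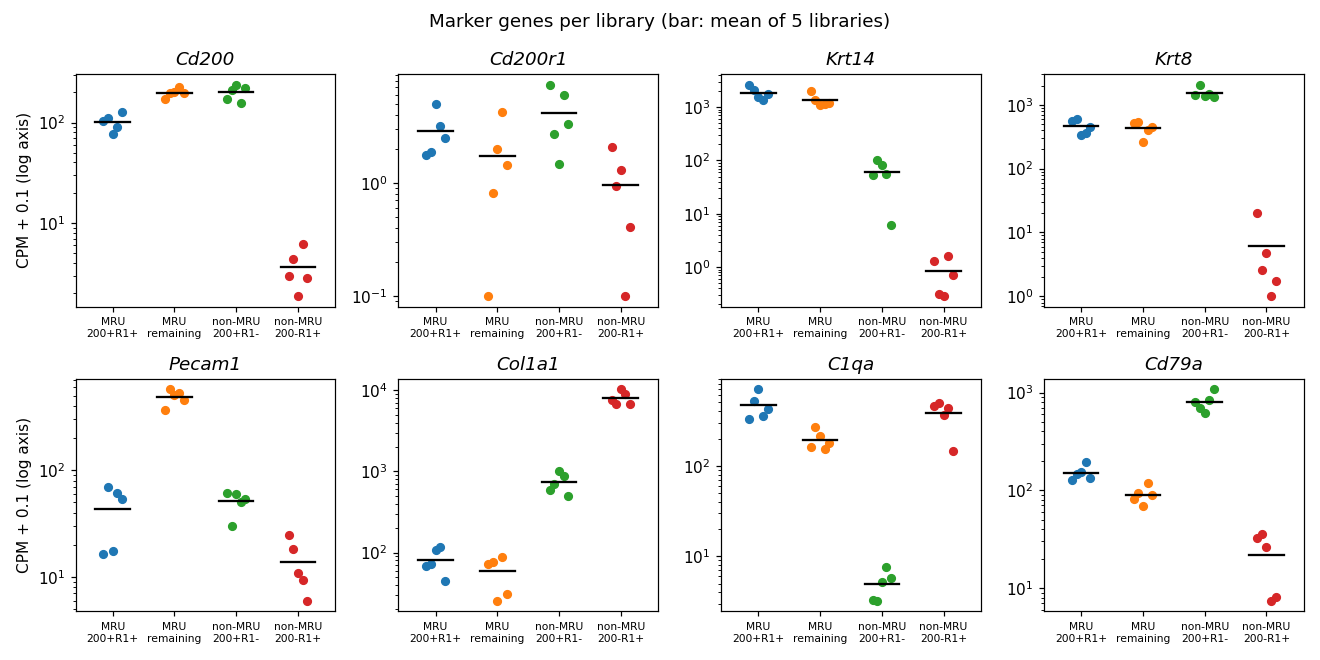
CPM of 8 genes in each library, on a log axis after adding a small constant, with 5 libraries per population and a bar at the mean. Col1a1 lies at 6690 CPM or more in each CD200R1+ non-MRU library and at 999 or less in the others, while Pecam1 lies at 368 or more in each remaining MRU library and at 69.5 or less in the others.

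The comparison within the MRU gate asked how CD200+CD200R1+ MRU differ from the remaining MRU. Markers of blood vessels and of fat were lower in CD200+CD200R1+ MRU. Flt1, a VEGF receptor of endothelial cells, stood at 6.55 ± 3.68 CPM against 301 ± 25.7 in remaining MRU, 45.8-fold lower (log2 SE 0.45, n = 5). Fabp4, a fatty acid carrier of adipocytes and capillaries, was 19.2-fold lower (log2 SE 0.35). The complement gene C1qa, a macrophage marker, was 2.39-fold higher (log2 SE 0.28), while the macrophage list had an adjusted p = 0.41 with an estimated correlation. Retnla, which is not on that list, stood at 8380 ± 3570 against 1760 ± 648 CPM, 4.76-fold (log2 SE 0.63), and did not pass in 6 of the 10 fits that left out a library. Mylk, the myosin light chain kinase, was 1.69-fold higher (log2 SE 0.22) but did not pass in 8 of the 10 fits that left out a library, and the basal and myoepithelial lists did not pass (adjusted p = 0.092 for each).

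Of 17236 genes tested, 1424 passed, 280 higher and 1144 lower in CD200+CD200R1+ MRU. At a fold of at least 2, 96 were higher and 747 lower. The higher genes numbered 169 without CD200+CD200R1+ MRU of mouse 4, 153 without that of mouse 5, 171 without remaining MRU of mouse 3 and 164 without that of mouse 4. At a fold of at least 2 they numbered 50 without CD200+CD200R1+ MRU of mouse 4, 61 without that of mouse 5 and 59 without remaining MRU of mouse 2. With DESeq2, the 10 MRU libraries alone and voom they numbered 152, 183 and 247. With the mouse number as a block 1719 genes passed, of which 429 (25%) were higher at any fold. In the authors' deposited table, 1549 genes lay below 0.05, 387 higher and 1162 lower. Higher genes made up 19.7% of calls, against 35.9% with the 10 MRU libraries alone (2546 genes), 38.7% with voom (3087 genes) and 30.3% with DESeq2.

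The genes with the largest rise were Fcna, a ficolin (ENSMUSG00000026938, chromosome 2, 25624666 to 25628030), 6.3-fold (log2 SE 0.45, adjusted p = 0.00034), the chemokine Ccl8, 5.36-fold (SE 0.49, adjusted p = 0.0023), the histidine ammonia-lyase Hal, 4.85-fold (SE 0.44, adjusted p = 0.0013), Retnla (adjusted p = 0.027), Wfdc17, 4.62-fold (SE 0.4, adjusted p = 0.00077), Cd209b, 4.56-fold (SE 0.53, adjusted p = 0.01), the interferon-induced Rsad2, 4.49-fold (SE 0.58, adjusted p = 0.021), and the chemokine Ccl6, 4.19-fold (SE 0.49, adjusted p = 0.0083). Cd209b belongs to a family of similar genes, which leaves its count uncertain. Ccl8 was 3.16-fold higher without the CD200+CD200R1+ library of mouse 4, where it reached 875 CPM. Retnla did not pass in 6 of the 10 fits that left out a library (adjusted p 0.0503 to 0.0737, and 0.000172 to 0.0737 over all alternatives), those without CD200+CD200R1+ MRU of mouse 3 or 4 or remaining MRU of mouse 2, 4, 5 or 6. Rsad2 did not pass in 3 (0.0572 to 0.0633, and 8.21e-06 to 0.0633 over all alternatives), those without CD200+CD200R1+ MRU of mouse 4 or remaining MRU of mouse 5 or 6.

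The genes with the largest fall were H2-M11, 287-fold (5 counts against 1508, log2 SE 0.66, adjusted p = 3e-08), the retinol-binding Rbp7 (ENSMUSG00000028996, chromosome 4, 149449687 to 149454978), 72.1-fold from 613 ± 73.2 CPM (SE 0.38, adjusted p = 1.9e-09), the growth factor Igf2, 65.1-fold (SE 0.62, adjusted p = 7.2e-07), the phosphatase Ptprr, 63.8-fold (SE 0.71, adjusted p = 4.5e-06), the carbonic anhydrase Car7, 49.3-fold (SE 0.78, adjusted p = 3.3e-05), Gkn3, 48.7-fold (SE 0.96, adjusted p = 0.00039), Flt1 (adjusted p = 3e-08) and Tmem255b, 45.7-fold (SE 0.47, adjusted p = 4.1e-07). H2-M11 is one of a family of similar genes, so its count is uncertain. Single CD200+CD200R1+ libraries moved some of these folds. Without mouse 2, H2-M11 had 1 count left and a count ratio of 1300 (234 to 51600), and Car7 was 80.3-fold lower. Without mouse 3, Igf2 was 124-fold, Ptprr 125-fold and Gkn3 81.2-fold lower.

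All 15 endothelial markers were lower, over all genes and adjusted over the list alone (median log2 fold change -3.77, adjusted p = 5.3e-40, and 0.0028 with an estimated correlation). They included Esam, 24.7-fold, Plvap, 17.7-fold, and Eng, 6.81-fold. Of 12 pericyte and smooth muscle markers, 10 were lower and none higher, 11 adjusted over the list alone (median -2.68, adjusted p = 9.5e-21, and 0.0016 with an estimated correlation). Ndufa4l2 was 9.23-fold, Notch3 5.37-fold, the potassium channel gene Kcnj8 12.2-fold and Cox4i2 4.56-fold lower. Of 11 adipocyte markers, 6 were lower and none higher, 7 adjusted over the list alone (median -2.72, adjusted p = 1.4e-09, and 0.0029 with an estimated correlation). Pparg, the adipocyte transcription factor, had a log2 fold change of -3.8, and Car3 was 8.19-fold and Adipoq 8.05-fold lower. The members Plin1, Cidec, Lipe, Cidea and Lep did not pass. Since Fabp4 also marks capillaries, a smaller share of fat cells was not told apart from one of vascular cells. Of 18 Notch pathway genes, 8 were lower and 1 higher, 9 and 2 adjusted over the list alone (median -0.78, adjusted p = 7e-07, and 0.025 with an estimated correlation). After Notch3, the smallest adjusted p belonged to Hey1, 4.57-fold lower, Notch1, 3.66-fold, and Notch4, 11.3-fold, and Notch3 is also on the pericyte list. The higher member was Notch2, named after its value was seen. Since the endothelial and pericyte lists fell too, bulk pools cannot tell lower Notch genes in MRU cells from a smaller share of vascular cells.

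Of 16 macrophage and myeloid markers, 9 were higher and none lower, 13 adjusted over the list alone (median 0.96, adjusted p = 1.2e-08, but adjusted p = 0.41 with an estimated correlation). Itgam was 3.71-fold higher, C1qa 2.39-fold, C1qc 2.22-fold and the adaptor gene Tyrobp 1.83-fold. C1qc did not pass without CD200+CD200R1+ MRU of mouse 4 (adjusted p = 0.0518, and 0.000269 to 0.0518 over all alternatives). Tyrobp did not pass without that library or remaining MRU of mouse 2 or 4 (0.0593 to 0.0863, and 0.00158 to 0.0863 over all alternatives). Of 17 lymphocyte markers, 1 was higher and none lower, over all genes and adjusted over the list alone (median 0.4, adjusted p = 0.039, but adjusted p = 0.75 with an estimated correlation). The list did not pass without CD200+CD200R1+ MRU of mouse 5 (0.055) or 6 (0.1) or remaining MRU of mouse 2 (0.081) or 4 (0.14), with a range of 0.011 to 0.75 over its alternatives, nor with fry (0.27).

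Of 30 cytosolic ribosomal protein genes, 10 were higher and none lower, 13 adjusted over the list alone (median 0.26, adjusted p = 4.3e-06, but adjusted p = 0.61 with an estimated correlation). Rpl22 was 1.36-fold, Rps14 1.32-fold and Rpl32 1.3-fold higher. Mean levels of the list in CD200+CD200R1+ MRU were uneven, from 1.81 CPM for Rps16 to 1573 for Rpl4, and the cause was not tested. Without a filter on low counts Rpl22, Rps14 and Rpl32 did not pass (adjusted p 0.058, 0.0836 and 0.103), the highest values over their alternatives, of which the lowest were 0.000486, 0.000229 and 0.000231. Rpl32 also failed without CD200+CD200R1+ MRU of mouse 5 or remaining MRU of mouse 3 (0.0532 to 0.0627). Of 22 immediate early and dissociation response genes, 4 were lower and none higher, 7 lower and 1 higher adjusted over the list alone (median -0.32, adjusted p = 0.017, but adjusted p = 0.61 with an estimated correlation). Ier2 was 1.68-fold, Zfp36 1.53-fold, Atf3 1.47-fold and Junb 1.44-fold lower. Junb did not pass without CD200+CD200R1+ MRU of mouse 4 or 5 or remaining MRU of mouse 5 (0.0552 to 0.072, and 0.000495 to 0.072 over all alternatives). The list did not pass without remaining MRU of mouse 2 (0.052, and 0.0014 to 0.61 over its alternatives). Of 18 EMT-associated genes, 3 were lower and 1 higher, 5 and 1 adjusted over the list alone (median -0.43, adjusted p = 0.017, but adjusted p = 0.61 with an estimated correlation). Snai1 was 7.89-fold, Zeb1 2.85-fold and Tcf4 1.72-fold lower, while Twist2 was 2.49-fold higher from a low level of 0.66 ± 0.318 CPM. As with the Notch genes, bulk pools cannot tell a fall of these genes in MRU cells from a smaller share of vascular cells. Twist2 did not pass without CD200+CD200R1+ MRU of mouse 2 or remaining MRU of mouse 2, 3 or 4 (0.0548 to 0.0883), nor with voom (0.0597), with a range of 0.0059 to 0.0883. The list did not pass without CD200+CD200R1+ MRU of mouse 6 (0.053, and 0.008 to 0.61 over its alternatives).

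Lists of basal identity, contraction and stem cells did not pass within the MRU gate at the preset correlation. Of 20 basal identity genes, 1 was higher and none lower, with none adjusted over the list alone (median 0.44, adjusted p = 0.092). The basal list passed with camera on ranks (adjusted p = 0.027, and 0.027 to 0.75 over its alternatives). It was Trp63, the basal transcription factor, 1.68-fold higher (adjusted p = 0.0496), and its call was lost in each of the 10 fits that left out a library (0.0615 to 0.118) and without a filter (0.0509), with a range of 2.26e-05 to 0.118. Of 17 myoepithelial contraction genes, 1 was higher and 1 lower, over all genes and adjusted over the list alone (median 0.41, adjusted p = 0.092). Mylk was higher and Des, also on the pericyte list, 6.31-fold lower. Mylk failed in 8 of the 10 fits (0.0512 to 0.0911, and 0.000103 to 0.0911 over all alternatives), passing only without CD200+CD200R1+ MRU of mouse 4 or remaining MRU of mouse 2. The myoepithelial list passed without those same libraries (0.039 and 0.038) and with camera on ranks (0.027), with a range of 0.027 to 0.75 over its alternatives. Of 20 stem-cell-associated genes, 6 were lower and none higher, over all genes and adjusted over the list alone (adjusted p = 0.092). The median was 0.17 and the mean -0.57. The lower members with the smallest adjusted p were Zeb1, Notch4, the endothelial cadherin gene Cdh5, 13.1-fold, and Procr, 6.39-fold. Of these, Cdh5 is also on the endothelial list and Notch4 on the Notch list. Lower levels of the stem-cell-associated genes in MRU cells again cannot be told from a smaller share of vascular cells. Of 20 interferon response genes, 2 were higher and 2 lower, 3 and 6 adjusted over the list alone (adjusted p = 0.58). Rsad2 and Ifit1, 2.08-fold, were higher, while Mx2, 2.57-fold, and Gbp3, 2.19-fold, were lower. Ifit1 did not pass without CD200+CD200R1+ MRU of mouse 3 or 4 or remaining MRU of mouse 3, 5 or 6 (0.0539 to 0.0897, and 0.0015 to 0.0897 over all alternatives). Of 20 interstitial collagen and matrix genes, 1 was higher and none lower, over all genes and adjusted over the list alone, namely Col16a1, 1.7-fold (adjusted p = 0.0039). That list had an adjusted p of 0.054, of 0.045 with the mouse number as a block and of 0.026 with camera on ranks. It also passed without CD200+CD200R1+ MRU of mouse 6 (0.0072) or remaining MRU of mouse 2 (0.022), 3 (0.017) or 5 (0.041), with a range of 0.0072 to 0.75. The list of Wnt targets and feedback had an adjusted p of 0.066 and passed with camera on ranks (0.027). It also passed without CD200+CD200R1+ MRU of mouse 5 (0.047) or remaining MRU of mouse 2 (0.031), with a range of 0.027 to 0.44.

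Of the sort markers, Cd200 was 1.95-fold lower in CD200+CD200R1+ MRU (log2 SE 0.2, adjusted p = 0.0023). Cd200r1 had a log2 fold change of 0.76 (SE 0.74, adjusted p = 0.65), Cd24a of -0.09 (SE 0.27, adjusted p = 0.92) and Itga6 of 0.45 (SE 0.21, adjusted p = 0.23). Itga6 passed with the MRU libraries alone (adjusted p = 0.028) and with voom (0.00362), with a range of 0.00362 to 0.417. In all, 9 of 39 lists passed, against 14 in a model of the 10 libraries alone, a number that 13 of 80 splits of those libraries reached, the real one included. The other splits mix the populations, here and in the comparisons below, so they cannot show how many list calls arose by chance.

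**Figure D2:**
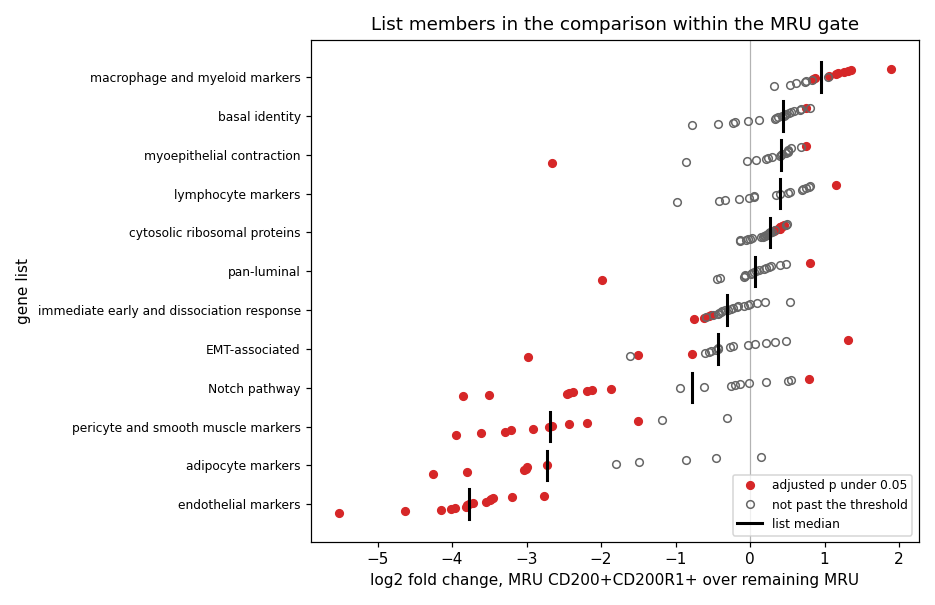
log2 fold change of each member of 12 gene lists between CD200+CD200R1+ MRU and remaining MRU, with filled points for genes past the threshold and a bar at the list median. The endothelial, adipocyte and pericyte lists have medians of -3.77, -2.72 and -2.68, and the macrophage list one of 0.96.

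The comparison outside the MRU gate set CD200+ against CD200R1+ non-MRU cells. Luminal epithelial genes were higher in CD200+ non-MRU. Csn3, a casein, stood at 7040 ± 3040 CPM against 6.15 ± 2.85, 1150-fold (log2 SE 0.54, n = 5), and Cldn3, a tight junction claudin, was 274-fold higher (log2 SE 0.3). Matrix genes were lower, with Sparc at 2170 ± 498 against 18300 ± 2890 CPM, 8.45-fold (log2 SE 0.17). With an estimated correlation the collagen and matrix list held (adjusted p = 0.0077), while the fibroblast list did not (adjusted p = 0.17). The macrophage gene C1qa stood at 4.88 ± 1.81 against 380 ± 140 CPM, and the B-cell gene Cd79a was 36.6-fold higher (log2 SE 0.37), while the macrophage and lymphocyte lists had adjusted p = 0.32 and 0.17 with an estimated correlation.

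Of 17236 genes, 9043 passed, 4107 higher and 4936 lower in CD200+ non-MRU. Below 0.05 in the authors' deposited table lay 9332 genes. With library size alone the split was 6822 higher and 3040 lower, a higher share of 69.2% against 45.4%. Without the CD200R1+ library of mouse 4, to which cells of mouse 3 had been added, 8593 genes passed.

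The genes with the largest rise included 3 without a count in CD200R1+ non-MRU, whose folds are lower bounds, so their rank among these genes is not known. Crb3, a regulator of epithelial polarity (ENSMUSG00000044279, chromosome 17, 57059105 to 57065918), was at least 538-fold higher (adjusted p = 6.2e-12). The immunoglobulin kappa segments Igkv12-46 and Igkv10-96 were at least 575-fold and 528-fold higher, with counts uncertain because the segments resemble each other. Ap1m2 and Ceacam10 each had 1 count in CD200R1+ non-MRU, in the library of mouse 2, and count ratios of 2150 (386 to 85100) and 2120 (380 to 83800). Without that library no count was left, and they were at least 583-fold and 581-fold higher. The milk protein genes Lalba and Csn2 were 1260-fold (log2 SE 0.69, adjusted p = 1.2e-10) and 1080-fold higher (SE 1.76, adjusted p = 5.6e-05). Csn2 varied widely, at 2360 ± 3510 CPM, and was 366-fold higher without CD200+ non-MRU of mouse 6 and 2360-fold without CD200R1+ non-MRU of mouse 6. With voom Csn2 did not pass (adjusted p = 0.189, and 1.5e-16 to 0.189 over all alternatives).

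The largest falls were those of the cytokine gene Il1a, 1510-fold (log2 SE 0.97, adjusted p = 1.2e-08), Lyz1, 171-fold (SE 1.53, adjusted p = 0.00034), the myeloid receptor gene Trem2, 116-fold (SE 0.54, adjusted p = 1.4e-09), the acute phase gene Saa3, 110-fold (SE 1.29, adjusted p = 0.00015), the retinoic acid-binding Crabp1, 96.3-fold (SE 0.85, adjusted p = 1.3e-06), the laminin gene Lamc3, 88.5-fold (SE 0.54, adjusted p = 2.7e-09), C1qc, 84.9-fold, and C1qa, 77.7-fold. Without CD200+ non-MRU of mouse 4, Il1a had 1 count left there and a count ratio of 11500 (2070 to 455000), and Crabp1 was 287-fold lower. Without CD200R1+ non-MRU of mouse 4, Lyz1 was 11.2-fold and Crabp1 59.6-fold lower. Without CD200+ non-MRU of mouse 5 Lyz1 was 261-fold lower, and without that of mouse 2 Trem2 was 195-fold lower. Saa3 was 63.4-fold lower without CD200R1+ non-MRU of mouse 6. Lyz1 did not pass with voom (0.0604, and 5.1e-08 to 0.0604 over all alternatives).

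All 18 pan-luminal genes were higher, over all genes and adjusted over the list alone (median 7.88, adjusted p = 1.1e-38, and 0.0012 with an estimated correlation). Cldn3 and the transcription factor gene Elf3, 498-fold, led the list. Of 20 epithelial junction genes, 19 were higher and none lower, over all genes and adjusted over the list alone (median 4.15, adjusted p = 3.6e-20, and 0.0016 with an estimated correlation), with the E-cadherin gene Cdh1 256-fold higher. Of 19 luminal progenitor genes, 13 were higher and 3 lower, over all genes and adjusted over the list alone (median 4.08, adjusted p = 6.5e-08, and 0.026 with an estimated correlation). Csn3 and Elf5, an alveolar transcription factor gene, 187-fold, had the smallest adjusted p. Of 12 milk protein genes, 9 were higher and 1 lower, 10 and 1 adjusted over the list alone (median 7.22, adjusted p = 2.5e-05, but adjusted p = 0.15 with an estimated correlation), Csn3 and Lalba first. Of 19 hormone-sensing luminal genes, 11 were higher and 2 lower, over all genes and adjusted over the list alone (median 1.17, adjusted p = 0.00087, but adjusted p = 0.15 with an estimated correlation). Prom1 was 237-fold and the prolactin receptor gene Prlr 59.5-fold higher. Without CD200R1+ non-MRU of mouse 2, Elf3 had 3 counts left there and a count ratio of 1020 (350 to 4970), Cdh1 was 472-fold higher, and Prom1, with no count left, at least 421-fold.

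Of 20 stem-cell-associated genes, 10 were higher and 4 lower, over all genes and adjusted over the list alone (median 0.79, adjusted p = 0.028, but adjusted p = 0.15 with an estimated correlation). Tspan8 was 267-fold and Sox9 10.8-fold higher, and Tspan8 539-fold without CD200R1+ non-MRU of mouse 3. The list did not pass without CD200R1+ non-MRU of mouse 6 (0.054), with camera on ranks (0.22) or with library size alone (0.071), with a range of 0.015 to 0.22 over its alternatives. Of 17 myoepithelial contraction genes, 8 were higher and 2 lower, over all genes and adjusted over the list alone (median 0.82, adjusted p = 0.041, but adjusted p = 0.62 with an estimated correlation). Lmod1 was 33.2-fold higher, at 4.39 ± 0.923 CPM, and the oxytocin receptor gene Oxtr 23.6-fold, at 5.95 ± 2.81 CPM. Without CD200R1+ non-MRU of mouse 3, Lmod1 had 3 counts left there and a count ratio of 58.1 (19.7 to 284). The list had an adjusted p of 0.051 with the mouse as a block and of 0.082 with library size alone, and did not pass without CD200R1+ non-MRU of mouse 5 (0.067) or CD200+ non-MRU of mouse 3 (0.067) or 4 (0.069), with a range of 0.017 to 0.62. Of 28 cell cycle genes, 12 were higher and none lower, over all genes and adjusted over the list alone (median 0.92, adjusted p = 0.017, but adjusted p = 0.84 with an estimated correlation), led by the replication genes Mcm7, 4.03-fold, and Mcm4, 2.23-fold. That list did not pass with library size alone (0.091, and 0.00071 to 0.84 over its alternatives). Of 15 antigen presentation genes, 10 were higher and none lower, 12 adjusted over the list alone (median 0.91, adjusted p = 0.0016, but adjusted p = 0.52 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, was 2.9-fold and Ciita, the regulator of MHC class II genes, 11.7-fold higher.

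Of 20 interstitial collagen and matrix genes, 19 were lower and none higher, over all genes and adjusted over the list alone (median -3.29, adjusted p = 1.9e-20, and 0.0077 with an estimated correlation), including Col5a1, 9.04-fold, and Col6a1, 12.2-fold. Of 18 EMT-associated genes, 15 were lower and none higher, over all genes and adjusted over the list alone (median -2.44, adjusted p = 5.4e-11, and 0.0077 with an estimated correlation). Sparc and the intermediate filament gene Vim, 5.6-fold, led it. Of 15 fibroblast markers, 11 were lower and 1 higher, over all genes and adjusted over the list alone (median -1.88, adjusted p = 3.1e-06, but adjusted p = 0.17 with an estimated correlation). The platelet-derived growth factor receptor genes Pdgfrb and Pdgfra were 14.2-fold and 6.09-fold lower, and 9 of the 15 genes stand on another list too. Of 20 basement membrane and laminin genes, 12 were lower and 7 higher, 13 and 7 adjusted over the list alone (median -1.87, adjusted p = 0.004, but adjusted p = 0.52 with an estimated correlation). The collagen IV gene Col4a1 was 14.7-fold lower and the epithelial laminin gene Lamb3 14.3-fold higher. Of 12 Hedgehog pathway genes, 8 were lower and 1 higher, 8 and 2 adjusted over the list alone (median -1.35, adjusted p = 0.0015, but adjusted p = 0.2 with an estimated correlation), with the coreceptor genes Gas1 15.4-fold and Boc 4.75-fold lower. Of 20 TGF-beta and BMP targets, 11 were lower and 4 higher, 11 and 5 adjusted over the list alone (median -0.8, adjusted p = 0.029, but adjusted p = 0.43 with an estimated correlation), with Tgfbr1 2.64-fold lower. With camera on ranks the basement membrane and TGF-beta lists did not pass (0.1 and 0.069), with ranges of 0.00088 to 0.52 and 0.007 to 0.43 over their alternatives. Of 21 inflammatory cytokine and chemokine genes, 14 were lower and 2 higher, over all genes and adjusted over the list alone (median -1.39, adjusted p = 0.0043, but adjusted p = 0.35 with an estimated correlation), led by Csf1, 4.51-fold lower, and Il1a. Members against their list, named after their values were seen, included the luminal progenitor genes Cd14, Rspo1 and Cxcl1, the hormone-sensing gene Tbx3 and the myoepithelial genes Smtn and Cald1, all lower. Higher were Pi16 of the fibroblast list, Hhip of the Hedgehog list and Csf3 and Il33 of the cytokine list.

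Of 16 macrophage and myeloid markers, 13 were lower and 2 higher, over all genes and adjusted over the list alone (median -3.71, adjusted p = 3.6e-07, but adjusted p = 0.32 with an estimated correlation), C1qa and C1qc first, and Ptprc and Laptm5, which lymphocytes also express, were the higher members. All 17 lymphocyte markers were higher, over all genes and adjusted over the list alone (median 2.18, adjusted p = 1.7e-08, but adjusted p = 0.17 with an estimated correlation), among them Cd79a. Cd200 was 56.4-fold higher (log2 SE 0.25, adjusted p = 3e-13), Cd24a 42.5-fold (SE 0.33, adjusted p = 2.6e-11) and Itga6 8.24-fold (SE 0.23, adjusted p = 8e-10). Cd200r1 was 4.66-fold higher in the CD200R1-negative population (SE 0.79, adjusted p = 0.022). It did not pass without CD200R1+ non-MRU of mouse 6 or CD200+ non-MRU of mouse 2 (0.0504 to 0.0604), nor with voom (0.0656), with a range of 0.00575 to 0.0656. In all, 18 lists passed, against 16 in a model of the 10 libraries alone, a number that 11 of 80 splits reached, the real one included.

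The direction of change inside and outside the MRU gate was compared over genes that passed in both comparisons, which share no library but come from the same mice. Of 908 such genes, 57.4% had the same sign. Both lower were 446 genes, against 327.6 expected of independent lists, and both higher were 75, against 66.7. The excess of genes higher in both depended on single libraries. They numbered 26, against 36.5, without CD200+CD200R1+ MRU of mouse 5 and 30, against 38.8, without remaining MRU of mouse 4. Without remaining MRU of mouse 5 they numbered 63, against 45.7. Genes higher in CD200+CD200R1+ MRU and lower in CD200+ non-MRU numbered 117, against 80.2, and those lower and higher 270, against 272.6. The 117 became 60, against 55, without remaining MRU of mouse 5 and 128, against 74.2, without CD200+CD200R1+ MRU of mouse 6. With the mouse number as a block, 511 genes were lower in both, against 376.5, and 106 higher in both, against 107.3. Higher and lower were then 203, against 125.2, and lower and higher 304, against 322.8, with 54.9% of the same sign. With library size alone the share of the same sign was 47.8%.

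CD200+CD200R1+ MRU were next compared with CD200+ non-MRU. Basal and contractile genes were higher in the MRU, with Trp63 at 127 ± 11.4 against 2.52 ± 1.73 CPM, 50.1-fold (log2 SE 0.3, n = 5), and Mylk 34.6-fold (SE 0.27). The macrophage list had an adjusted p = 0.15 with an estimated correlation, with the mannose receptor gene Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) at 300 ± 75.7 against 1.73 ± 1.11 CPM, 174-fold (SE 0.51). Fibroblast genes were lower, with Dcn, decorin, at 657 ± 60.5 against 8040 ± 2500 CPM, 12.2-fold (SE 0.23). Of 17236 genes, 8359 passed, 4125 higher and 4234 lower, and 8565 lay below 0.05 in the authors' deposited table.

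The genes with the largest rise in CD200+CD200R1+ MRU over CD200+ non-MRU were Cd209b, 175-fold (log2 SE 0.74, adjusted p = 6.3e-08), Mrc1, Retnla, 169-fold (SE 0.8, adjusted p = 1.9e-07), the interferon gene Ifnb1, 143-fold (SE 0.73, adjusted p = 8.8e-08), and Oasl1, 124-fold (SE 0.52, adjusted p = 1.3e-09). Those with the largest fall were Pi16, 149-fold (SE 0.67, adjusted p = 2.3e-08), the complement gene C7, 114-fold (SE 0.83, adjusted p = 9.5e-07), Gdf10, 102-fold (SE 0.55, adjusted p = 4.5e-09), the Wnt antagonist gene Sfrp4, 80.7-fold (SE 0.61, adjusted p = 4.4e-08), and Akr1c14, 79.2-fold (SE 0.54, adjusted p = 8.5e-09). Cd209b was 449-fold higher without CD200+ non-MRU of mouse 6, and Akr1c14 121-fold lower without CD200+CD200R1+ MRU of mouse 5. The lists that held with an estimated correlation numbered 5. Basal identity had 16 of 20 genes higher and 1 lower (median 3.77, adjusted p = 2.8e-14, estimated 0.0045), with Trp63 and the neuregulin gene Nrg1, 21.5-fold. Myoepithelial contraction had 15 of 17 higher (median 4.14, adjusted p = 1.9e-20, estimated 0.0045), with Mylk and Smtn, 16.2-fold. Integrins and hemidesmosomes had 12 of 16 higher (median 1.39, adjusted p = 1.4e-10, estimated 0.014), with Itga3, 11.4-fold, and Itga6, 14-fold. Wnt targets and feedback had 13 of 18 higher and 2 lower (median 2.09, adjusted p = 2.7e-05, estimated 0.016), with Fzd7, 26.6-fold, and Nkd2, 6.11-fold. Fibroblast markers had 13 of 15 lower and 1 higher (median -3.61, adjusted p = 1.8e-18, estimated 0.016), with Cd34, 18.6-fold, and Dcn. Adjusted over the list alone, each of these 5 counts was the same. Against their lists, and named after their values were seen, Thy1 of the basal list and Lef1 and Myc of the Wnt list were lower and Postn of the fibroblast list was higher.

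Other cell types also differed between these populations. Of 16 macrophage and myeloid markers, 13 were higher and 2 lower in CD200+CD200R1+ MRU, over all genes and adjusted over the list alone (median 4.11, adjusted p = 1.1e-12, but adjusted p = 0.15 with an estimated correlation), with C1qa 95.3-fold and C1qc 109-fold higher. Of 17 lymphocyte markers, 16 were lower and none higher, 17 adjusted over the list alone (median -2.43, adjusted p = 2.9e-08, but adjusted p = 0.2 with an estimated correlation), with Coro1a 5.88-fold and the T-cell gene Cd3e 13.4-fold lower. Of 7 tested mitochondrial genome genes, 5 were higher and none lower, over all genes and adjusted over the list alone (median 0.62, adjusted p = 0.014, but adjusted p = 0.51 with an estimated correlation), with mt-Nd4 2.28-fold and mt-Nd6 1.85-fold higher. Cd200 was 1.96-fold lower (log2 SE 0.2, adjusted p = 0.00036). Cd200r1 had a log2 fold change of -0.55 (SE 0.72, adjusted p = 0.55) and Cd24a of -0.37 (SE 0.27, adjusted p = 0.27). In all, 17 lists passed, against 16 in a model of the 10 libraries alone, a number that 8 of 80 splits reached, the real one included.

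Against CD200R1+ non-MRU, CD200+CD200R1+ MRU had higher pan-luminal, epithelial junction and myoepithelial genes. Of 20 basal identity genes, 15 were higher and 5 lower, over all genes and adjusted over the list alone (median 5.42, adjusted p = 9.1e-08, but adjusted p = 0.07 with an estimated correlation). The basal keratin genes Krt17 and Krt14 stood at 1980 ± 680 and 1880 ± 498 CPM against 0.654 ± 0.199 and 0.744 ± 0.594, 2990-fold (log2 SE 0.59, n = 5) and 2520-fold (SE 0.69). Matrix genes were lower, with the proteoglycan gene Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703) at 127 ± 33.3 against 16100 ± 5000 CPM, 126-fold (SE 0.41). Of 17236 genes, 8074 passed, 3930 higher and 4144 lower, and 8284 lay below 0.05 in the authors' deposited table. With library size alone 6943 were higher and 2514 lower, a higher share of 73.4% against 48.7%. Without the CD200R1+ library of mouse 4, to which cells of mouse 3 had been added, 7890 passed.

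In this comparison Col9a2 had 1 count in CD200R1+ non-MRU, in the library of mouse 6, and a count ratio of 8180 (1470 to 323000). Without that library it had no count left and was at least 2190-fold higher. Il17b was 3420-fold higher (log2 SE 0.56, adjusted p = 5.1e-13), and the hemidesmosome collagen gene Col17a1 2340-fold (SE 0.61, adjusted p = 3e-12). Without CD200R1+ non-MRU of mouse 2, Col17a1 had 2 counts left there and a count ratio of 4290 (1190 to 35400). The largest falls besides Lum were those of Kera, 327-fold (SE 1.15, adjusted p = 3.4e-06), Adamts19, 188-fold (SE 0.52, adjusted p = 1.2e-10), Scg3, 179-fold (SE 0.68, adjusted p = 8.6e-09), and Igsf21, 115-fold (SE 0.84, adjusted p = 6.4e-07). Kera was 523-fold lower without CD200+CD200R1+ MRU of mouse 6. The lists that held with an estimated correlation numbered 7. All 18 pan-luminal genes were higher (median 5.92, adjusted p = 4.3e-29, estimated 0.0019), with Gata3 27.3-fold and Esrp1 142-fold. All 20 epithelial junction genes were higher (median 3.73, adjusted p = 3.7e-19, estimated 0.0019), with Cdh1 301-fold and Cldn3 47.4-fold. Myoepithelial contraction had 15 of 17 higher (median 5.28, adjusted p = 4.8e-20, estimated 0.0068), with Oxtr 744-fold and Lmod1 348-fold. Stem-cell-associated genes had 10 of 20 higher and 4 lower (median 1.11, adjusted p = 0.0075, estimated 0.044), with Lgr6 93.6-fold and the Notch ligand gene Dll1 368-fold. That list did not pass with camera on ranks (0.15, and 0.0053 to 0.15 over its alternatives). All 15 fibroblast markers were lower (median -5.34, adjusted p = 5e-29, estimated 0.0019), with Pdgfra 40.4-fold and Dcn 44.9-fold. Interstitial collagens and matrix had 17 of 20 lower and 1 higher (median -4.55, adjusted p = 4.3e-29, estimated 0.0019), with Col5a1 22-fold and Col6a1 33.4-fold. EMT-associated genes had 15 of 18 lower and 2 higher (median -2.75, adjusted p = 1.7e-13, estimated 0.0068), with the fibronectin gene Fn1 61.7-fold and Vim 6.05-fold. Adjusted over the list alone, 11 stem-cell-associated genes were higher and the other counts were the same. Against their lists, and named after their values were seen, Zeb1, Zeb2, Nes and Nr2f1 of the stem-cell list were lower, and Snai2 and Cdh2 of the EMT list and Col16a1 were higher. Without CD200R1+ non-MRU of mouse 2, Esrp1 was 318-fold and Cdh1 557-fold higher, and without that of mouse 3 Lmod1 had 3 counts left there and a count ratio of 611 (209 to 2970).

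Cd200 was 28.7-fold higher in CD200+CD200R1+ MRU than in CD200R1+ non-MRU (log2 SE 0.24, adjusted p = 8.5e-13), Cd24a 32.9-fold (SE 0.32, adjusted p = 3e-11) and Itga6 116-fold (SE 0.27, adjusted p = 3.5e-14). Cd200r1 had a log2 fold change of 1.67 (SE 0.78, adjusted p = 0.087). It passed without CD200R1+ non-MRU of mouse 2 (0.0424), with library size alone (0.033) and with DESeq2 (0.0449), with a range of 0.033 to 0.178. In all, 13 lists passed, against 14 in a model of the 10 libraries alone, a number that 20 of 80 splits reached, the real one included.

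The remaining MRU had higher basal genes than CD200+ non-MRU. Vascular and fat genes were higher at the preset correlation, but with an estimated correlation the endothelial, pericyte and adipocyte lists had adjusted p = 0.093, 0.18 and 0.062. Rbp7 stood at 613 ± 73.2 against 1.98 ± 1.51 CPM, 309-fold (log2 SE 0.43, n = 5), and Fabp4 at 4770 ± 804 against 111 ± 37.5 CPM, 42.8-fold (SE 0.37). Mylk was 20.5-fold higher (SE 0.26). Pcolce2 and the fibroblast marker Pi16 were 78.7-fold (SE 0.6) and 74-fold (SE 0.63) lower. Of 17236 genes, 7608 passed, 4146 higher and 3462 lower.

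In remaining MRU against CD200+ non-MRU, the adipsin gene Cfd had no count in the latter and was at least 553-fold higher (adjusted p = 1.4e-06). The globin gene Hbb-bs, with 1 count in CD200+ non-MRU (mouse 5), had a count ratio of 2360 (423 to 93300), and H2-M11, with 2 counts (mouse 6), one of 796 (220 to 6580), both uncertain as members of similar families. Hbb-bs had a count ratio of 1340 (241 to 53200) without remaining MRU of mouse 2, was at least 620-fold higher without CD200+ non-MRU of mouse 5, which left no count there, and did not pass with voom (0.0924, and 0.000112 to 0.0924 over all alternatives). H2-M11 was at least 434-fold higher without CD200+ non-MRU of mouse 6, which left no count there, and Rbp7 469-fold without that of mouse 4. Btnl9 was 223-fold higher (log2 SE 0.64, adjusted p = 5.9e-09). Inmt was 91.7-fold (SE 0.64, adjusted p = 6.5e-08), Sfrp4 69.1-fold (SE 0.61, adjusted p = 6.8e-08) and C7 65.9-fold lower (SE 0.78, adjusted p = 2.4e-06), with C7 334-fold lower without remaining MRU of mouse 5. The lists that held with an estimated correlation numbered 4. Basal identity had 16 of 20 higher and 1 lower (median 3.48, adjusted p = 5.6e-13, estimated 0.0083), with Trp63 29.7-fold and Nrg1 16.6-fold. All 17 myoepithelial contraction genes were higher (median 3.74, adjusted p = 1.5e-19, estimated 0.0083), with Smtn 11.4-fold. Integrins and hemidesmosomes had 11 of 16 higher and 1 lower (median 1.39, adjusted p = 4.5e-10, estimated 0.015), with Itga3 9.96-fold and Itga6 10.3-fold. Fibroblast markers had 13 of 15 lower and 2 higher (median -3.65, adjusted p = 1.5e-19, estimated 0.015), with Dcn 14.9-fold and the gelsolin gene Gsn 20.2-fold. Adjusted over the list alone, 12 integrin and hemidesmosome genes were higher and the other counts were the same. Members that went against their list, named after their values were seen, were Thy1 and Itgb3, lower, and Pdgfrb and Postn, higher.

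Of 15 endothelial markers, 14 were higher in remaining MRU than in CD200+ non-MRU and none lower, over all genes and adjusted over the list alone (median 5.11, adjusted p = 1.9e-12, but adjusted p = 0.093 with an estimated correlation), with Flt1 92.2-fold and Esam 20.1-fold. Of 12 pericyte markers, 9 were higher and none lower, 11 adjusted over the list alone (median 1.56, adjusted p = 0.00065, but adjusted p = 0.18 with an estimated correlation), with Cox4i2 5.82-fold and Rgs5 30.9-fold. Of 11 adipocyte markers, 9 were higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.00031, but adjusted p = 0.062 with an estimated correlation), with Fabp4 and Pparg, 9.36-fold, first. Macrophage markers had 12 of 16 higher and 2 lower, 13 and 2 adjusted over the list alone (median 3.13, adjusted p = 1.2e-07, but adjusted p = 0.22 with an estimated correlation), with C1qa 39.9-fold and C1qc 49.1-fold. Lymphocyte markers had 16 of 17 lower and none higher, over all genes and adjusted over the list alone (median -2.84, adjusted p = 3.3e-12, but adjusted p = 0.062 with an estimated correlation), with Coro1a 9.57-fold and Cd52 5.84-fold. Cd200 (log2 fold change -0.01, SE 0.19, adjusted p = 0.98), Cd200r1 (-1.31, SE 0.74, adjusted p = 0.16) and Cd24a (-0.28, SE 0.27, adjusted p = 0.42) did not pass. Cd200r1 passed with voom (0.0425, and 0.0425 to 0.35 over all alternatives). In all, 19 lists passed, against 21 in a model of the 10 libraries alone, a number that 2 of 80 splits reached, the real one included.

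Against CD200R1+ non-MRU, the remaining MRU had higher pan-luminal and myoepithelial genes. Of 20 basal identity genes, 15 were higher and 5 lower, over all genes and adjusted over the list alone (median 5.34, adjusted p = 5.3e-07, but adjusted p = 0.08 with an estimated correlation). Krt17 stood at 1550 ± 574 and Krt14 at 1370 ± 376 CPM, 2340-fold (log2 SE 0.58, n = 5) and 1840-fold higher (SE 0.68), and the vascular gene Flt1 was 187-fold higher (SE 0.52). Lum was 152-fold lower (SE 0.41), at 106 ± 42.7 CPM. Of 17236 genes, 7595 passed, 3867 higher and 3728 lower. With library size alone 6639 were higher and 2258 lower, a higher share of 74.6% against 50.9%. Without the CD200R1+ library of mouse 4, to which cells of mouse 3 had been added, 7382 passed.

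For remaining MRU against CD200R1+ non-MRU, Col9a2 had a count ratio of 5570 (999 to 220000) and was at least 1480-fold higher without CD200R1+ non-MRU of mouse 6, which left no count there. Tmem255b had no count in CD200R1+ non-MRU and was at least 481-fold higher (adjusted p = 2e-09), and Il17b was 2330-fold higher (log2 SE 0.56, adjusted p = 1.2e-12). Kera was 349-fold (SE 1.17, adjusted p = 3.7e-06), Adamts19 228-fold (SE 0.54, adjusted p = 1.2e-10), Crabp1 153-fold (SE 0.89, adjusted p = 7.1e-07) and the BMP regulator gene Bmper 146-fold lower (SE 0.4, adjusted p = 3.8e-12). Without remaining MRU of mouse 2, Kera had 2 counts left there and a count ratio of 1910 (530 to 15800), and Crabp1 was 94.9-fold lower without CD200R1+ non-MRU of mouse 4. The lists that held with an estimated correlation numbered 7. All 18 pan-luminal genes were higher (median 5.82, adjusted p = 1.3e-30, estimated 0.0012), with Cldn3 45.6-fold and Gata3 15.6-fold. All 20 epithelial junction genes were higher (median 3.37, adjusted p = 2.1e-19, estimated 0.0012), with Cdh1 215-fold. Myoepithelial contraction had 15 of 17 higher (median 4.88, adjusted p = 1.4e-19, estimated 0.0077), with Oxtr 463-fold and Lmod1 237-fold. Stem-cell-associated genes had 11 of 20 higher and 4 lower (median 2.13, adjusted p = 0.00016, estimated 0.0055), with Lgr6 67.2-fold and Dll1 251-fold. All 15 fibroblast markers were lower (median -5.56, adjusted p = 1.3e-30, estimated 0.0012), with Pdgfra 47-fold and Dcn 54.9-fold. Interstitial collagens and matrix had 18 of 20 lower and 1 higher (median -4.91, adjusted p = 1.8e-35, estimated 0.0012), with Col5a1 28.1-fold and Dcn. EMT-associated genes had 13 of 18 lower and 3 higher (median -2.13, adjusted p = 1.1e-10, estimated 0.012), with Twist2 80.3-fold and Fn1 41.9-fold. Adjusted over the list alone, 16 myoepithelial genes were higher, 19 collagen and matrix genes and 14 EMT-associated genes were lower, and the other counts were the same. Cdh1 was 397-fold higher without CD200R1+ non-MRU of mouse 2, and without that of mouse 3 Lmod1 had 3 counts left there and a count ratio of 417 (143 to 2030).

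All 15 endothelial markers were higher in remaining MRU than in CD200R1+ non-MRU, over all genes and adjusted over the list alone (median 4.72, adjusted p = 1.1e-10, but adjusted p = 0.11 with an estimated correlation), with Esam 109-fold and Flt1 first. Of 12 pericyte markers, 8 were higher and 1 lower, over all genes and adjusted over the list alone (median 1.89, adjusted p = 0.018, but adjusted p = 0.39 with an estimated correlation). Rgs5 was 77.4-fold higher, or 137-fold without CD200R1+ non-MRU of mouse 3, and Pdgfrb 7.29-fold lower. Of 11 adipocyte markers, 8 were higher and none lower, over all genes and adjusted over the list alone (median 2.68, adjusted p = 0.0081, but adjusted p = 0.17 with an estimated correlation). The lipase gene Lipe was 6.39-fold higher, and Cidea, with 1 count in CD200R1+ non-MRU (mouse 2), had a count ratio of 131 (23.2 to 5210). Without that library it had no count left and was at least 35.7-fold higher. Cd200 was 56.1-fold (log2 SE 0.25, adjusted p = 1.4e-13), Cd24a 34.9-fold (SE 0.32, adjusted p = 2.9e-11) and Itga6 84.8-fold higher (SE 0.27, adjusted p = 8.5e-14). Cd200r1 had a log2 fold change of 0.91 (SE 0.79, adjusted p = 0.38). In all, 17 lists passed, and also 17 in a model of the 10 libraries alone, a number that 9 of 80 splits reached, the real one included.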

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

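Tests chosen only after the result was seen were those of scaling for all 3 patterns weighed here and those of a mislabelled library and of stromal cells for the keratins, while both tests of a varying share of other cells and the counts of splits were set before.

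Of 359 groups of 5 libraries, of a named gene or of library totals, 34 had a library far from the others, by the ratio of its gap to the nearest library to the range of the group on the log2 scale. Chance gives about 1 in 20 for independent groups. Where 1 library held the only counts of a gene, the ratio was 1 by construction, and named genes are not independent. The count of 34 therefore cannot be set against that rate. In CD200+ non-MRU, 8 of the 34 lay in the library of mouse 6. It was low for Cd34 (ratio 0.75, 426 CPM against 735 to 885), Csf1 (0.81, 70.4 against 123 to 140), Dcn (0.74, 3880 against 8040 to 10400), Gas1 (0.77, 3.51 against 10.4 to 14.3), Mylk (0.83, 17 against 34.4 to 39.6), Pcolce2 (0.72, 140 against 333 to 468) and Pi16 (0.8, 139 against 382 to 493). It held the only counts of H2-M11 in that population (1, 0.163 CPM). Without it, 8542 genes passed between the non-MRU populations, 7932 between CD200+CD200R1+ MRU and CD200+ non-MRU and 7163 between remaining MRU and CD200+ non-MRU. In the same population, mouse 5 held the only count of Hbb-bs (ratio 1, 0.0735 CPM) and mouse 4 was high for Il1a (0.74, 0.603 CPM against 0 to 0.0789).

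In CD200R1+ non-MRU, the library of mouse 2 was apart for 6 genes. It held the only counts of Ap1m2, Ceacam10 and Cidea (ratio 1 and 0.109 CPM for each) and of Prom1 (1, 0.655 CPM), and was high for Cdh1 (0.73, 0.873 CPM against 0.0932 to 0.209) and Esrp1 (0.78, 1.2 against 0.0932 to 0.209). Mouse 6 held the only count of Col9a2 (1, 0.102 CPM) and was low for C1qa (0.74, 146 against 361 to 499) and Esam (0.93, 0.102 against 2.84 to 3.43). The library of mouse 4, to which cells of mouse 3 had been added, was low for Csn3 (0.73, 1.68 against 6.1 to 9.6).

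In CD200+CD200R1+ MRU, the library of mouse 3 was low for 4 genes, Adipoq (ratio 0.81, 0 CPM against 0.583 to 0.898), Car3 (0.73, 1.62 against 7.51 to 12.9), Notch4 (0.77, 0.492 against 1.5 to 2.04) and Scg3 (0.84, 0.211 against 1.6 to 2.19). Mouse 4 was high for Ccl8 (0.85, 875 against 162 to 210). Mouse 2 was high for Dll1 (0.71, 159 against 95.5 to 111) and Itga6 (0.89, 1380 against 1040 to 1070), and mouse 6 low for Col5a1 (0.81, 36 against 52.2 to 56.8) and Oxtr (0.89, 130 against 199 to 209). In remaining MRU, mouse 2 was low for Cdh5 (0.8, 130 against 165 to 175) and Trp63 (0.75, 59.7 against 75.3 to 81.3) and high for Dll1 (0.78, 117 against 66.6 to 75.3). Mouse 6 was low for Gkn3 (0.71, 5.85 against 23.1 to 39.6) and Rgs5 (0.74, 382 against 497 to 546).

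Endothelial genes were lower in CD200+CD200R1+ MRU than in remaining MRU. Scaling of the libraries was argued against, since it moves all genes alike, while the median log2 fold change of the list lay -3.79 from the median of 1000 random lists of like expression, whose medians ran from -0.41 to 0.4. Within the remaining MRU libraries the 15 genes moved together more than such lists (percentile 100, mean correlation 0.59 against a 95th percentile of 0.1). Endothelial cells in the sorted pool may therefore contribute, with Flt1 at 301 CPM. Regulation of these genes in common would give the same correlation and stays open, and the lineage depletion and the MRU gate were meant to remove such cells. Of the 15 genes, 1 is on another list too.

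Of 16 macrophage genes, 9 were higher in CD200+CD200R1+ MRU than in remaining MRU, with an adjusted p = 0.41 for the list with an estimated correlation. Scaling was argued against by a median log2 fold change 0.97 above that of 1000 random lists of like expression, whose medians ran from -0.36 to 0.25. Within the CD200+CD200R1+ libraries the 16 genes moved together more than such lists (percentile 100, mean correlation 0.61 against a 95th percentile of 0.19), so a varying share of macrophages may contribute, with C1qa at 466 CPM. Common regulation stays open here too, lineage depletion was meant to remove such cells, and 2 of the 16 genes are on another list.

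Keratin genes were near 0 in CD200R1+ non-MRU, whose cells the labels call epithelial. A single mislabelled library was argued against, since Krt14, Krt8 and Epcam lay below all libraries of the other populations in 5 of its 5 libraries. Scaling was argued against by a median log2 fold change of 8.27 for the pan-luminal list with library size alone. Of 15 fibroblast markers, 11 were higher in this population in each of its 3 comparisons, so stromal cells may make up much of the sorted pool, with Dcn at 29500 CPM and Sparc at 18300. Lineage depletion and a sort of epithelial cells were meant to remove such cells, and 9 of those 15 markers are on another list. All pan-luminal genes were lower in this population in each of its 3 comparisons. Epcam stood at 4.53 and Cdh1 at 0.3 CPM, against means of at least 541 and 63.55 in the other populations. These values argue against an epithelial state that keeps luminal genes beside matrix genes. A state of epithelial origin that has lost them was not tested.

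In models of the 10 libraries of each pair, 1 of 80 splits, the real split, reached the real gene count in all 6 comparisons. Each other split put libraries of both populations into each of its groups, so differences between populations added to the spread within groups. Few calls were therefore likely in those splits whatever the cause. The splits thus cannot show how many of the real calls arose by chance. The real counts were 2546 within MRU, 7227 between the non-MRU populations, 8165 and 6734 for CD200+CD200R1+ MRU against CD200+ and CD200R1+ non-MRU, and 8089 and 6609 for remaining MRU against the same. The highest of the other splits gave 2 within MRU and 0 elsewhere. For the number of lists, the bound set before the data were examined left chance not excluded in 5 comparisons. The other splits mix the populations here too, so they cannot decide the number of lists in any of the 6 comparisons. Within MRU, 13 of 80 splits gave as many as the real 14 (highest other 20). Between the non-MRU populations it was 11, with 16 real and 20 highest. For CD200+CD200R1+ MRU it was 8 against CD200+ non-MRU (16 real, 20 highest) and 20 against CD200R1+ non-MRU (14 real, 19 highest). For remaining MRU it was 9 against CD200R1+ non-MRU (17 real, 21 highest) and 2 against CD200+ non-MRU, where another split also gave the real 21. Besides the real split, 9 splits parted all pairs of the same mouse, with 0 genes each.

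For the share of genes with the same sign within MRU and between the non-MRU populations, 2 of 80 splits were as high as the real 52%, with 100% the highest other. By the bound set before the data were examined, fewer than 4 would have excluded chance. That bound was wrong, because only 2 splits had genes called in both comparisons and the others gave no value. Chance therefore stays open, a reading decided after the result was seen.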

How the results depend on the processing

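None of the tests in this part was chosen after the results were seen. Across 229 values of named genes, the mouse as a block and median-of-ratios scaling kept each direction and side of the threshold. DESeq2 and library size each left 228 as they were and brought 1 past the threshold. Without a filter 224 stayed, 4 fell below the threshold and 1 reversed. With 10 libraries alone 224 stayed, 1 passed and 4 gave no value, their genes being removed by the filter. With voom 221 stayed, 5 fell below, 2 passed and 1 reversed. Of the fits without a library, 2233 values stayed, 48 fell below, 1 passed and 8 reversed.

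The reversed values were those of genes that had not passed. Cd200 between remaining MRU and CD200+ non-MRU had a log2 fold change of 0.037 without a filter and 0.065 with voom, and of -0.044 to 0.104 without single libraries. Cd24a within MRU ranged from -0.21 to 0.054, positive among those fits only without CD200+CD200R1+ MRU of mouse 4. The cause was not tested.

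Genes changed within MRU numbered 1424, but 2546 with the 10 libraries alone and 3087 with voom. With 10 libraries alone, counts fell from 9043 to 7227 between the non-MRU populations. They fell from 8074 to 6734 and from 7595 to 6609 for CD200+CD200R1+ and remaining MRU against CD200R1+ non-MRU. Against CD200+ non-MRU they went from 8359 to 8165 and from 7608 to 8089. The main fit shares its spread over all 20 libraries, so calls within MRU also depend on the non-MRU libraries. The cause of these shifts was not tested. Without single libraries, counts were 1072 to 1283 within MRU, 8542 to 9271 between the non-MRU populations, 7720 to 8061 and 7650 to 8218 for CD200+CD200R1+ MRU against CD200+ and CD200R1+ non-MRU, and 6923 to 7305 and 7064 to 7697 for remaining MRU against the same.

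In the same order of comparisons, lists called numbered 9, 18, 17, 13, 19 and 17. With an estimated correlation they numbered 4, 5, 5, 7, 4 and 7, since that correlation widens the error of a list. Camera on ranks called 16 within MRU, and fry called 28 and 27 for the MRU populations against CD200R1+ non-MRU. The cause was not tested. Without single libraries they numbered 8 to 10, 17 to 18, 16 to 18, 13 to 14, 17 to 20 and 16 to 18.

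The share of genes with the same sign within MRU and between the non-MRU populations was 57.4%, but 47.8% with library size alone, where the median of all genes between the non-MRU populations moved from -0.056 to 0.365. Without single libraries it ranged from 55.8 to 62, the latter without remaining MRU of mouse 5. Where a population held 0 to 3 counts of a gene, depth limited the fold to a lower bound or to a count ratio with a wide interval.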
